A study of Mus musculus with 8 samples.

How the data were processed

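RNA sequencing of mouse (C57BL/6) MLL-ENL leukaemia was analysed in 8 libraries: Hhex+/fl and Hhex-/fl tumours from bone marrow and Hhex+/fl and Hhex-/fl leukaemia cell lines, with 2 libraries in each of the 4 groups. RNA was isolated with an RNeasy kit and libraries were made with a TruSeq RNA kit, per the labels' protocols, which mention sorted GFP-positive leukaemia cells without tying the sort to these samples. Strand is not stated.

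The deposited table of the whole series holds whole-number counts per gene, identified by Entrez Gene ID and symbol. Per the submitters' processing notes, Subread, featureCounts and limma were used with the mouse build mm9; their versions and roles are not given in the sources used here. The deposited file of each sample holds log2 RPKM values for 14484 genes, with no other processing stated in the labels; they were used only in an alternative. The count table has 26286 genes, of which 8065 have 0 counts in all 8 libraries. A spreadsheet had turned 27 symbols into dates; these were restored through the Entrez Gene ID with a RefSeq gene table of the assembly GRCm38, in which 24176 of the IDs were found. In 549 genes the symbol was NA. Because that assembly differs from the authors' build, no coordinates are given and the table was used only for names and for which genes neighbour each other.

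Totals per library were 11839413 to 14480455 counts. Genes with low counts were removed with filterByExpr by group (minimum count 10, minimum total 15), which left 13108 genes holding at least 99.93% of the counts of each library. CPM were computed with TMM scaling. The main test was edgeR 4.0.16 (R 4.3.3), a quasi-likelihood F test on 1 fit of 4 group means over all 8 libraries, with 4 residual degrees of freedom and a prior of 2.58, and a common biological coefficient of variation of 0.238. P-values were adjusted by Benjamini and Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. The comparisons were Hhex-/fl minus Hhex+/fl in tumours, the same in cell lines, their mean, their difference, and cell lines minus tumours averaged over genotypes. Standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. They are unreliable for changes near 0. Groups were compared for overlap of all libraries. Calls in tumours and cell lines were compared by count; Fisher's exact test was run but its p is not used, since the calls share the dispersions of 1 fit.

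Before the data were examined, the tests, the main alternatives, 27 gene lists (signalling and growth programmes, chromatin complexes and markers of blood and stromal lineages) and the rule for naming genes were fixed. The rule names Hhex, Cdkn2a, Cdkn2b, Ezh2, Suz12 and Eed always, up to 4 called members of each list, and the 6 largest rises and 6 largest falls without overlap at a mean of at least 5 CPM; for the difference between responses it names the 5 smallest adjusted p. Predicted genes without a standard symbol were counted but not named. Lists were tested with camera (two-sided, preset inter-gene correlation 0.01), adjusted over 54 tests for tumours and cell lines together and over the 27 lists for each other comparison. Camera with an estimated correlation and fry were run beside it.

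Alternatives were DESeq2 1.42.0, limma 3.58.1 voom with and without quality weights, other scalings (DESeq2 size factors, upper quartile, library size), no filter and CPM filters of 1 and 5 in 2 libraries, a replicate block, only the 4 libraries compared, an additive model, a minimum fold of 1.5, and leaving out each library in turn. Without 1 library a group holds a lone sample, assumed to vary like the other groups. Chosen after seeing the data were limma-trend on the log2 RPKM values and a covariate of the log2 summed CPM of Rn18s, Rn28s1 and Lars2, genes whose reads can come from ribosomal RNA. The averaged and material comparisons were repeated over 34 splits of the 8 libraries, and figures and tests on single explanations were made in Python 3.11.15. No outlier test was made, since no group has 4 libraries.

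The fits were tested on simulated counts drawn from the real means and library sizes with a seeded set of genes changed. In the tumour comparison 20% of genes changed 2-fold and 78% changed 4-fold were recovered, and 5 of 12772 unchanged genes were called; in cell lines it was 36% and 67%, with 13 of 12763. In the averaged comparison 60% and 81% were recovered, and in cell lines minus tumours 56% and 88%. Whether the simulated spread matched that of each real group was not tested. Counts of the real cell line pairs differed by more than those of the tumour pairs. The chi-square per degree of freedom was 34.5 and 54.5 in Hhex+/fl and Hhex-/fl cell lines, and 16.5 and 14.6 in the tumours. The shares recovered with cell lines may therefore be too high. In the real lines Cdkn2a and Cdkn2b, 6.29-fold and 19.5-fold apart, did not pass over all genes. Genes that share reads with near-identical copies, overlapping genes and antisense genes are uncertain.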

Results

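Gene expression was measured by RNA sequencing in mouse MLL-ENL leukaemia, a myeloid leukaemia driven by a fusion of the MLL gene, with a wild-type allele (Hhex+/fl) or a null allele (Hhex-/fl) of Hhex beside a floxed one. Hhex encodes a homeobox transcription factor. The labels do not say whether the floxed allele had been recombined. The deposited counts name the Hhex+/fl samples Het and the Hhex-/fl samples KO, as if the floxed allele were deleted, without stating it. Both genotypes were sampled as tumours from bone marrow and as leukaemia cell lines, giving 4 groups of 2 libraries. Gene counts summed to 14400418 and 12564084 in Hhex+/fl tumours, 13316742 and 14480455 in Hhex-/fl tumours, 11839413 and 13661867 in Hhex+/fl cell lines, and 12837584 and 12705485 in cell lines labelled Hhex-/fl. The labels do not say whether the 2 libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Counts of the 2 libraries differed by far more than sampling noise in each group, with a chi-square per degree of freedom of 14.6 to 54.5. No pair was therefore 1 library deposited again, which leaves open whether a pair came from 1 animal or culture.

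Hhex (Entrez Gene 15242) was lower in Hhex-/fl tumours, at 97.6 and 80.7 CPM, than in Hhex+/fl tumours, at 152 and 161 CPM. The means were 89.1 ± 11.9 and 156 ± 6.6 CPM (SD, n = 2). In cell lines the order was the opposite: the libraries labelled Hhex-/fl held 110 and 89.8 CPM, and those labelled Hhex+/fl 50.7 and 42.9 CPM. Hhex therefore goes against the genotype label in the cell lines, and every direction given for them is by label. The log2 fold change was -0.81 (SE 0.15) in tumours and 1.09 (SE 0.16) in cell lines; neither passed over all genes in edgeR (adjusted p = 0.129 and 0.214), and both passed adjusted over the list alone, the 6 genes fixed in advance (adjusted p = 0.00416 and 0.000808). Over all genes Hhex passed in DESeq2 (adjusted p = 0.000895 in tumours and 2.67e-06 in cell lines). In tumours it also passed in limma-voom with quality weights (0.0189) and with the 4 tumours alone (0.0324). With a replicate block within each material it passed in tumours and cell lines (edgeR adjusted p = 0.00727 and 0.0091), though the labels do not tie replicate numbers across groups. The table gives 1 count per whole gene, so reads from any part of Hhex that a deletion leaves would be included.

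Gene expression separated the tumours from the cell lines first. The first principal component held 64.2% of the variance and ran from -65.4 to -57.1 in tumours and from 35.1 to 83.5 in cell lines. The second, with 15.9%, parted the cell line libraries by replicate number, at 37.8 and 32.9 against -42.8 and -55.6. The third, with 8.6%, parted the genotypes, from 10.6 to 32.7 in Hhex+/fl libraries and from -30.6 to -11.5 in libraries labelled Hhex-/fl.

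**Figure D1:**
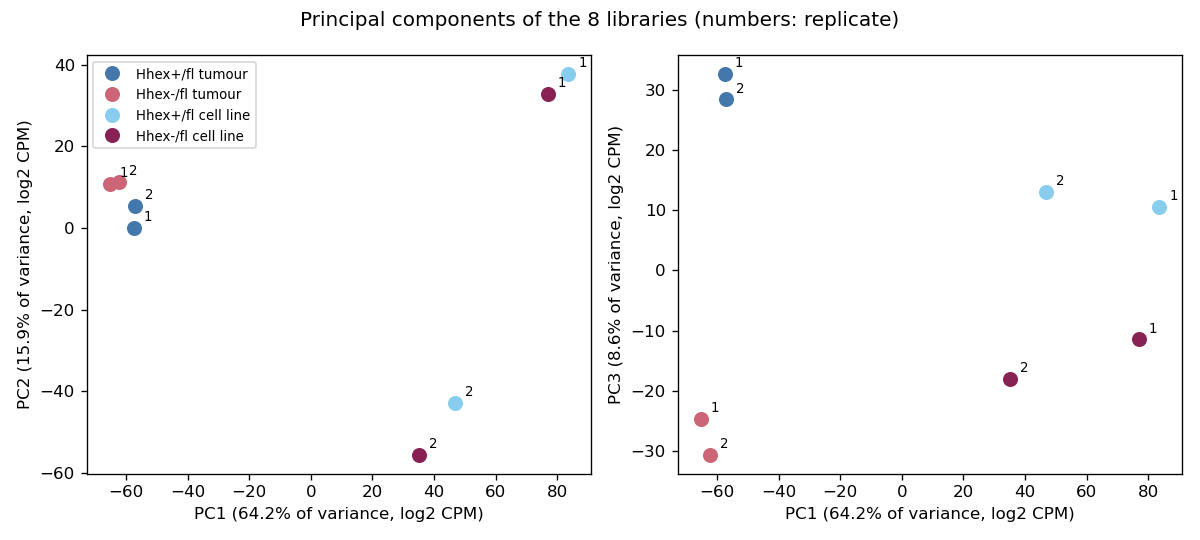
Principal components of log2 CPM of the 8 libraries, each point a library and each colour a group. The first axis holds 64.2% of the variance and parts tumours from cell lines, and the second holds 15.9% and parts the cell lines by replicate number.

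The comparison of tumours asked which genes depend on Hhex in leukaemia in the animal. Chpf (Entrez Gene 74241), which encodes a chondroitin polymerizing factor, rose 28.4-fold in Hhex-/fl tumours, from 3.9 ± 1.1 to 111 ± 0.6 CPM (SD, n = 2). Its adjacent gene Tmem198 rose from 0.6 to 21.9 CPM, and Hoxa11, a homeobox gene of the Hoxa cluster, from 0.1 and 0.5 CPM to 11.98 and 7.55 CPM. Other genes of the Hoxa cluster, chosen after their values were seen, did not pass: the log2 fold change was 0.16 for Hoxa9, 0.54 for Hoxa10 and -0.26 for Hoxa7. The antisense gene Hoxa11os, also chosen after its values were seen, stood at 3.94 (adjusted p = 0.0783). Interferon-induced genes rose with them: Oas2, an oligoadenylate synthetase, rose 5.48-fold, from 33.8 ± 5.0 to 186 ± 6.1 CPM, and Irf9, part of the factor that acts after type I interferon, rose 2.62-fold, from 58.6 ± 5.2 to 153 ± 0.3 CPM. Samd4, an RNA-binding protein gene, rose 14.4-fold.

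In all, 23 genes rose and 4 fell among 13108 tested in edgeR at an adjusted p under 0.05. The rises in Chpf (log2 4.83, SE 0.30), Tmem198 (5.27, SE 0.42), Rtp4 (4.05, SE 0.29), Irf9 (1.39, SE 0.10), Oas2 (2.45, SE 0.18) and Oas1a (1.37, SE 0.11) each had an adjusted p of 0.0144. Samd4 (3.85, SE 0.36) and Zbp1 (2.81, SE 0.25) had 0.0188, and Hoxa11 0.0232. The 4 that fell were Arhgef10l (log2 -1.43, SE 0.12), Padi2 (-1.31, SE 0.12), which encodes an enzyme that citrullinates proteins, Iffo1 (-0.76, SE 0.09) and Socs2, a suppressor of cytokine signalling, at 3.8 and 11.1 CPM in Hhex+/fl and 0.2 and 0.1 CPM in Hhex-/fl tumours. All 27 had no overlap between genotypes, which follows largely from the call itself and adds no support. Of all genes 51.7% had none, against 33.3% by chance. The count moved with the test, from 9 with a minimum fold of 1.5 to 55 in limma-voom. It was 337 with the 4 tumours fitted alone, 349 in DESeq2 and 873 with a replicate block within material. It fell to 1 with a ribosomal RNA covariate. The lean toward rises moved too: 85.2% of calls were higher here and 64% in limma-voom with quality weights (212 higher and 119 lower). With the 4 tumours alone it was 61.1% (206 and 131). It was 53.3% in DESeq2 (186 and 163) and 49.5% with a replicate block within material (432 and 441). The count of calls fell when any single tumour library was left out, though a group then held a lone sample.

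The series title asks about repression of Cdkn2a through PRC2, a histone methyltransferase complex. Cdkn2a (Entrez Gene 12578), which encodes cell cycle inhibitors, stood at 44.1 and 59.0 CPM in Hhex-/fl tumours and at 12.9 and 6.5 CPM in Hhex+/fl tumours, 5.30-fold apart (log2 2.41, SE 0.51). Its neighbour Cdkn2b (Entrez Gene 12579), an inhibitor of CDK4 and CDK6, stood at 4.9 and 4.6 against 0.8 and 0.6 CPM, 6.39-fold apart (log2 2.68, SE 0.35). Neither passed over all genes (adjusted p = 0.156 and 0.0618), and both passed adjusted over the list alone, the 6 fixed genes (adjusted p = 0.00504 and 0.000963). The call over all genes depended on the test. Both passed in DESeq2 (adjusted p = 2.69e-05 and 0.000323), in limma-voom with quality weights (0.0281 and 0.0091) and with the 4 tumours alone (0.0339 and 0.0263). With a replicate block within material both passed too (edgeR adjusted p = 0.00613 and 0.00455). Cdkn2b also passed with no filter (0.036) and on log2 RPKM (0.0469). The Cdkn2a log2 fold change was 1.66 with the ribosomal RNA covariate and 3.01 without Hhex+/fl tumour 1. The PRC2 core genes Ezh2 (log2 0.05, SE 0.24), Suz12 (0.38, SE 0.16) and Eed (0.11, SE 0.09) did not pass, at edgeR adjusted p = 0.975, 0.477 and 0.740. These are mRNA levels only, and PRC2 activity at Cdkn2a was not measured.

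**Figure D2:**
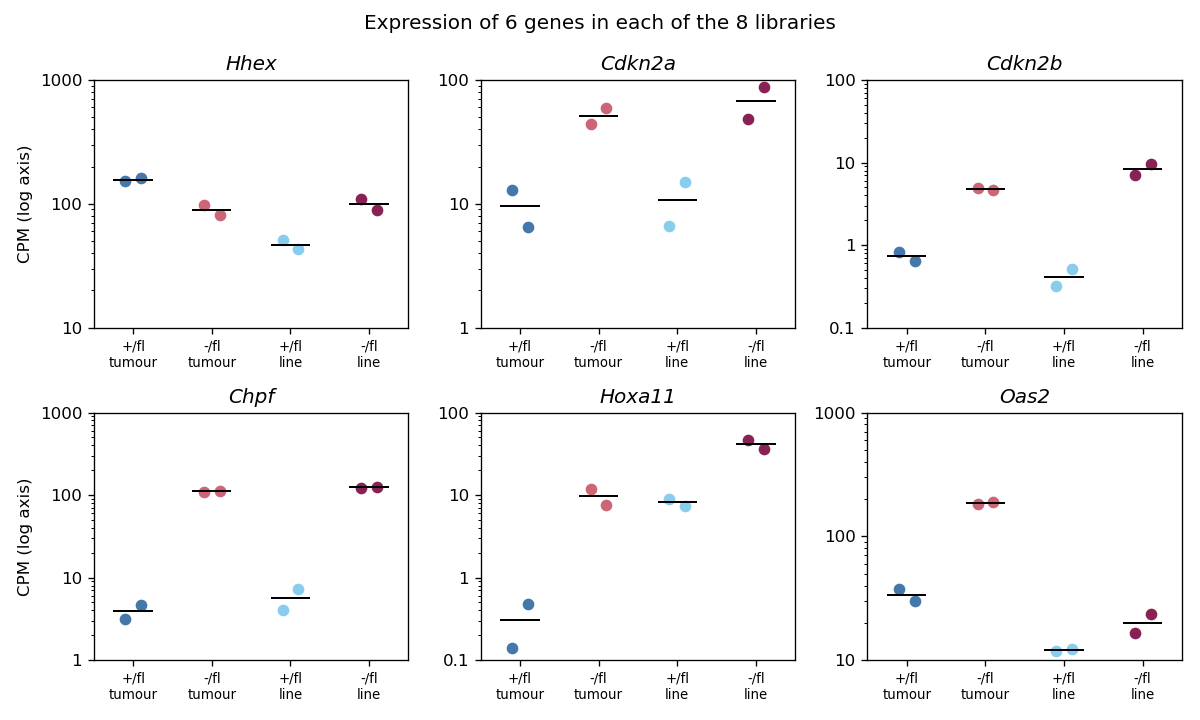
CPM on a log axis of 6 genes in each of the 8 libraries (points) with the mean of each group (line). Chpf and Cdkn2b were higher in each library labelled Hhex-/fl than in each Hhex+/fl library, and Hhex was lower in Hhex-/fl tumours and higher in cell lines labelled Hhex-/fl.

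Interferon response genes had the smallest adjusted p of the 27 lists in tumours. All 38 measured members were higher in Hhex-/fl tumours, with a median log2 fold change of 1.37; 12 rose over all genes and 32 rose adjusted over the list alone. Camera gave the list an adjusted p of 2.6e-104, and adjusted p = 0.0798 with an estimated correlation. Ribosomal RNA reads were 0.34% and 0.59% of the counts in Hhex-/fl tumours and 0.75% and 2.15% in Hhex+/fl tumours. Neutrophil maturation genes were also higher there, in 35 of 38 (median 0.65), with none past the gene test (camera adjusted p = 3.17e-05, and adjusted p = 0.809 with an estimated correlation). With the ribosomal RNA covariate the interferon median was 1.25, with camera adjusted p = 3.41e-42, and the neutrophil median turned to -0.43.

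Of 7 measured CDK inhibitors, 3 rose adjusted over the list alone, Cdkn2b, Cdkn2a and Cdkn1c (log2 1.39, SE 0.41), and none over all genes; the median was 0.59 (camera adjusted p = 0.0018, and adjusted p = 0.343 with an estimated correlation). With the ribosomal RNA covariate it was 0.32 and the call ended (adjusted p = 0.0554). G1/S genes lay slightly higher, in 40 of 42 (median 0.23, adjusted p = 1.53e-06, and adjusted p = 0.809 with an estimated correlation), with none past the gene test. Primary granule genes (median 0.29), T and NK lineage genes (1.37) and erythroid lineage genes (1.12), such as Slc4a1 at 3.93 (SE 0.99), lay higher with none past it (camera adjusted p = 0.0378, 0.0105 and 7.01e-05). Each of these 3 had adjusted p = 0.343 with an estimated correlation. The erythroid call ended with a filter of 5 CPM in 2 libraries (median 0.27, adjusted p = 0.186) and with the ribosomal RNA covariate (median 0.42, adjusted p = 0.177). Haemoglobin genes of the erythroid list are near-identical copies whose reads may be split between them. Stromal and endothelial genes had 3 members that fell adjusted over the list alone, Pdgfrb (log2 -1.84), Acta2 (-1.25) and Eng (-1.34), and a median of -0.12 (camera adjusted p = 0.0342, and adjusted p = 0.343 with an estimated correlation). Megakaryocyte and platelet genes (median -0.57, with Itgb3 at -1.08 lower adjusted over the list alone), sterol synthesis genes (-0.22) and immediate early genes (-0.15) lay lower (camera adjusted p = 0.0474, 0.0474 and 0.0446; each adjusted p = 0.809 with an estimated correlation). Members named from a count adjusted over the list alone, and Slc4a1, were chosen after their values were seen.

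The other 16 lists did not pass in tumours, with a smallest adjusted p of 0.154 and medians from -0.47 to 0.16. Hoxa11 was the 1 of 25 MLL-fusion target genes that rose, and Socs2 the 1 of 22 cytokine (STAT5) response genes that fell. Medians were 0.04 over 12 PRC2 subunits and 0.004 over 19 PRC1 subunits. Of 63 Polycomb-repressed developmental regulators, 4 were expressed enough to be tested. Calls of weaker lists passed or missed the threshold by which libraries were fitted, often with medians that stayed as large. Primary granule genes missed it without Hhex+/fl tumour 2 (median 0.33, adjusted p = 0.157) or Hhex-/fl tumour 2 (0.17, 0.218). Sterol synthesis genes did so without Hhex+/fl tumour 1 (-0.18, 0.0525) or 2 (-0.14, 0.0803), Hhex-/fl tumour 1 (-0.10, 0.542), or the cell lines labelled Hhex-/fl 1 (-0.21, 0.0608) or 2 (-0.21, 0.0548). Immediate early genes did so without Hhex+/fl tumour 1 (-0.17, 0.179), Hhex-/fl tumour 1 (-0.20, 0.16) or 2 (-0.31, 0.18), or the cell line labelled Hhex-/fl 1 (-0.14, 0.0777). For megakaryocyte and platelet genes it was Hhex+/fl tumour 2 (-0.34, 0.289), Hhex-/fl tumour 1 (-0.58, 0.0961) or 2 (-0.37, 0.0696), and Hhex+/fl cell line 1 (-0.57, 0.0651) or 2 (-0.57, 0.0701). For stromal and endothelial genes it was Hhex+/fl tumour 2 (-0.01, 0.155), Hhex-/fl tumour 1 (-0.40, 0.232) or 2 (-0.27, 0.377), Hhex+/fl cell line 2 (0.14, 0.0534), and the cell lines labelled Hhex-/fl 1 (-0.03, 0.126) or 2 (-0.03, 0.123), and with no filter their median was 0.22. Immediate early and megakaryocyte genes also missed it with no filter (-0.13, 0.0743 and -0.43, 0.154), with upper quartile scaling (-0.18 and -0.60, each 0.0598) and with library size alone (-0.19, 0.0613 and -0.61, 0.0596). With the ribosomal RNA covariate immediate early genes had a median of -0.17 and an adjusted p of 0.452. Medians of lists that still passed moved as well. CDK inhibitors had 0.89 and 0.21 without Hhex-/fl tumour 1 and 2, T and NK lineage genes 0.61, 0.82 and 0.65 without Hhex+/fl tumour 1, Hhex-/fl tumour 1 and 2 and 0.84 with the covariate, and erythroid genes 1.87, 1.92 and 0.51 without Hhex+/fl tumour 1, 2 and Hhex-/fl tumour 1. G1/S genes had 0.41 with the covariate, and immediate early genes -0.28 with a filter of 5 CPM in 2 libraries. Stromal genes had -1.25 with that filter, -0.45 with the covariate, and 0.13 and 0.14 without Hhex+/fl tumour 1 and Hhex+/fl cell line 1.

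The comparison of cell lines asked which genes differ by genotype label in cultured leukaemia cells. Chpf was the 1 gene that passed: it rose 21.6-fold, from 4.1 and 7.3 CPM in lines labelled Hhex+/fl to 123 and 125 CPM in lines labelled Hhex-/fl (log2 4.44, SE 0.29, edgeR adjusted p = 0.0264). Tmem198 stood at 0.8 and 12.1 CPM (log2 3.98) and Hoxa11 at 8.9 and 7.4 against 46.5 and 36.3 CPM (log2 2.34), and neither passed. Cdkn2a stood at 48.4 and 87.7 CPM in lines labelled Hhex-/fl against 6.7 and 14.9 CPM, 6.29-fold apart (log2 2.65, SE 0.51). Cdkn2b stood at 7.1 and 9.5 against 0.3 and 0.5 CPM, 19.5-fold apart (log2 4.28, SE 0.38).

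Neither Cdkn2a nor Cdkn2b passed over all genes in cell lines (adjusted p = 0.214 and 0.0939), and both passed adjusted over the list alone (adjusted p = 0.00305 and 8.6e-05). Over all genes Cdkn2a passed in DESeq2 (adjusted p = 6.27e-06) and Cdkn2b with no filter (0.0361). With a replicate block within material both passed (edgeR adjusted p = 0.0096 and 0.00848). The Cdkn2a log2 fold change was 1.43 with the ribosomal RNA covariate and 3.35 without Hhex+/fl cell line 2, and that of Cdkn2b 3.65 with the covariate and 3.58 on log2 RPKM. The PRC2 core genes Ezh2 (log2 0.02), Suz12 (0.04) and Eed (-0.02) did not pass. Unadjusted p was under 0.05 for 2108 genes, against 655 by chance; 42.2% of genes had no overlap between the labels, against 33.3% by chance. Differences between replicates 1 and 2 correlated across genes between the genotype labels at 0.885, though nothing in the labels ties these numbers. The count of calls was 344 in DESeq2 and 1474 with a replicate block within material (837 higher and 637 lower). It was 0 with the 4 libraries fitted alone, with a ribosomal RNA covariate, and without Hhex+/fl tumour 1 or 2, Hhex-/fl tumour 1 or 2, or either cell line labelled Hhex-/fl, and 2 without Hhex+/fl cell line 1.

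In cell lines 10 lists passed camera by label, none of them with an estimated correlation, and no member of them passed over all genes. Nucleolar and MYC-linked genes were positive in 1 of 33 (median -0.34), and 8 fell adjusted over the list alone, among them Nop2 (log2 -0.62, SE 0.14) and Nolc1 (-0.50, SE 0.12) (camera adjusted p = 5.89e-12, and adjusted p = 0.343 with an estimated correlation). Of 42 G1/S genes 0 were positive (median -0.33, adjusted p = 1.69e-11, and adjusted p = 0.609 with an estimated correlation), and of 40 G2/M genes 2 were (median -0.25, adjusted p = 8.29e-07, and adjusted p = 0.809 with an estimated correlation). Of 31 p53 target genes, 29 were positive and 7 rose adjusted over the list alone, with Ccng1 at 0.98, Btg2 at 0.90 and Fas at 0.87 (median 0.55, adjusted p = 3.39e-09, and adjusted p = 0.391 with an estimated correlation). Interferon response genes were positive in 30 of 38 (median 0.64); adjusted over the list alone, 18 rose, such as Zbp1 (1.55, SE 0.25) and Isg15 (1.39, SE 0.30), and 2 fell, Stat2 (-0.37) and Psmb8 (-0.41). Their camera adjusted p was 5.89e-12, with adjusted p = 0.343 with an estimated correlation, and with the ribosomal RNA covariate the median was 0.26 (adjusted p = 0.0366). P53 target genes had 0.28 with that covariate and 0.34 without the line labelled Hhex-/fl 2, G2/M genes -0.11 without that line, and G1/S genes -0.54 and -0.17 without the lines labelled Hhex-/fl 1 and 2. These members were chosen after their values were seen.

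Of 19 secretory and inflammatory genes, 9 rose adjusted over the list alone, such as Nfkbia (0.91, SE 0.12) and Tnfaip3 (1.16, SE 0.18), inhibitors of NF-kB signalling, and Il1rn (1.88, SE 0.32), the interleukin-1 receptor antagonist gene. Vegfa (-0.47) and Csf1 (-1.15) fell adjusted over the list alone (camera adjusted p = 7.52e-05, and adjusted p = 0.184 with an estimated correlation). CDK inhibitors had a median of 0.96, with Cdkn2b and Cdkn2a higher adjusted over the list alone (adjusted p = 1.63e-06, and adjusted p = 0.184 with an estimated correlation). ATF4 and ER stress genes had a median of -0.39 with none past the gene test (adjusted p = 7.52e-05, and adjusted p = 0.276 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.19, with Pfkl (-0.71) and Pfkp (-0.53) lower adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.343 with an estimated correlation); without the cell line labelled Hhex-/fl 1 the adjusted p was 0.272, and the median was -0.38 with the ribosomal RNA covariate and -0.11 without Hhex+/fl cell line 2. The median of CDK inhibitors was 0.58 without the line labelled Hhex-/fl 1. Members named here outside the CDK inhibitors were chosen after their values were seen.

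Neutrophil maturation genes had a median of 0.48 in cell lines (camera adjusted p = 0.0409, and adjusted p = 0.809 with an estimated correlation) that turned without single libraries. It was -0.04 (adjusted p = 0.556) without Hhex+/fl cell line 1 and -1.34 (adjusted p = 5.55e-05) without the line labelled Hhex-/fl 2, and 1.65 and 1.22 without Hhex+/fl cell line 2 and the line labelled Hhex-/fl 1. Without Hhex-/fl tumour 1 or 2 the median stayed at 0.48 (adjusted p = 0.0569 and 0.0527), and it was -1.31 with the ribosomal RNA covariate. Ribosomal RNA reads were 0.51% and 0.24% of counts in lines labelled Hhex-/fl and 1.68% and 1.27% in lines labelled Hhex+/fl. With that covariate the G1/S call (median -0.12, camera adjusted p = 0.0728) and the ATF4 and ER stress call (-0.14, 0.0548) also ended. The other 17 lists did not pass, with a smallest adjusted p of 0.184; medians were 0.34 for monocyte and macrophage, -0.65 for mast cell, basophil and eosinophil, 0.83 for the 2 tested B lineage and 0.27 for stem and progenitor genes.

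**Figure D3:**
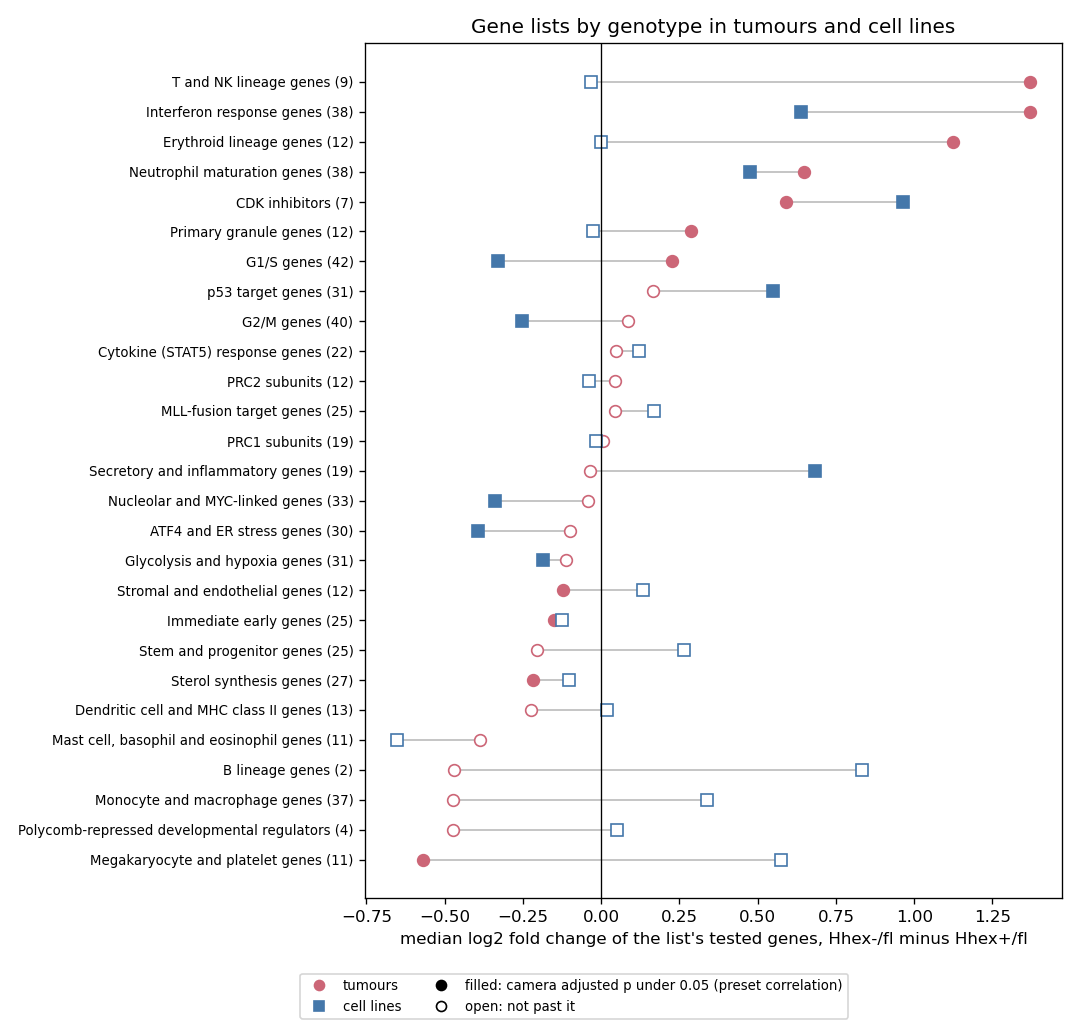
Median log2 fold change of the tested members of each of 27 gene lists, Hhex-/fl minus Hhex+/fl by label, in tumours (circles) and cell lines (squares), with the number of tested genes in brackets. Filled symbols passed camera with a preset correlation; interferon response genes had medians of 1.37 and 0.64.

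Averaged over tumours and cell lines, 35 genes rose and 4 fell with the Hhex-/fl label (edgeR, n = 4 libraries against 4). Cdkn2b rose 11.2-fold (log2 3.48, SE 0.26, adjusted p = 0.0157), and Cdkn2a was 5.77-fold apart without passing (2.53, SE 0.36, adjusted p = 0.0585). Cdkn2a passed in DESeq2 (5.55e-12), with no filter (0.0203) and with a replicate block within material (0.00195). Its log2 fold change was 2.71 without the line labelled Hhex-/fl 1 and 1.54 with the ribosomal RNA covariate. Cdkn2b missed the threshold with that covariate (2.94, adjusted p = 0.471). It also did without Hhex+/fl tumour 1 (3.59, 0.0558) or 2 (3.40, 0.0999), Hhex-/fl tumour 1 (3.46, 0.117) or 2 (3.51, 0.119), Hhex+/fl cell line 2 (3.67, 0.0559) or the line labelled Hhex-/fl 2 (3.37, 0.0528). Chpf rose 24.8-fold, Tmem198 24.7-fold, Hoxa11 12.6-fold and Sbf2, a myotubularin-related gene, 13.5-fold (log2 3.75, SE 0.46). Mier2 (-0.69, SE 0.09) and Iffo1 (-0.65, SE 0.06) fell. The antisense gene Hoxa11os also rose, chosen after its values were seen, and its reads cannot be told from those of Hoxa11 because no strand is stated. Among all genes, 13.5% had no overlap with the same direction in both materials, against 5.6% by chance.

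Interferon response genes led the averaged lists as well: 15 of 38 rose over all genes and 30 adjusted over the list alone (median 0.99, camera adjusted p = 7.76e-74, and adjusted p = 0.0909 with an estimated correlation). Among CDK inhibitors 1 of 7 rose over all genes, Cdkn2b, and 4 adjusted over the list alone (median 0.79, adjusted p = 2.82e-07, and adjusted p = 0.104 with an estimated correlation). Of the 27 lists 10 passed, and none kept its call with an estimated correlation. The count of 39 genes was 22 in limma-voom, 11 in an additive model and 0 with a ribosomal RNA covariate. The lean toward rises was weaker where the count was 462, in DESeq2 (307 higher and 155 lower), or 1603, with a replicate block within material (906 and 697). The count also depended on single libraries. Without 1 library it was 2 or 1 (Hhex+/fl tumour 1 or 2), 1 (Hhex-/fl tumour 1 or 2), 11 or 4 (Hhex+/fl cell line 1 or 2), 100 (line labelled Hhex-/fl 1) and 3 (line labelled Hhex-/fl 2).

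Tumours and cell lines were then compared in their response to genotype. Material went with the sex of the cells, as given below, so culture cannot be told here from sex or animal of origin. Padi2 was lower in Hhex-/fl tumours and stood at 14.1 against 6.9 CPM in cell lines labelled Hhex-/fl, a difference between responses of -2.34 on the log2 scale (adjusted p = 0.0814). Arhgef10l (-1.50), Irf9 (1.21), Glipr1 (-1.50) and Hhex (-1.90) each had an adjusted p of 0.242. No gene passed this test in the main edgeR fit, where 1366 had an unadjusted p under 0.05. DESeq2 called 116, limma-voom 0, and edgeR with a replicate block within material 305. Of all genes, 8.1% moved in opposite directions without overlap in both materials, against 5.6% by chance.

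Chpf was the 1 gene shared between the 23 rises in tumours and the 1 in cell lines. No p is given for this overlap, since both calls come from 1 fit with shared dispersions and it rests on a single call in cell lines. Of the 27 genes called in tumours, 25 had the same sign without overlap in cell lines. Fold changes in both materials correlated weakly across genes, which are not independent replicates (Pearson r = 0.222, Spearman rho = 0.16), and the value depended on the fit. Pearson r was 0.065 without Hhex+/fl cell line 2, 0.112 without the line labelled Hhex-/fl 1, 0.079 in DESeq2 and 0.054 with no filter. It was 0.787 (rho 0.493) with the ribosomal RNA covariate. That covariate has 1 coefficient per gene for both materials and was lower in every library labelled Hhex-/fl. It therefore shifts both fold changes together, and this value is no sign of shared response. The overlap was 0 in the fits that lost the cell line call, 47 in DESeq2 and 156 with a replicate block within material.

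Interferon response genes differed between the 2 responses by a median of 0.82, with 19 adjusted over the list alone higher in tumours (camera adjusted p = 4.96e-23, and adjusted p = 0.293 with an estimated correlation). All 42 G1/S genes differed in the positive direction (median 0.56, adjusted p = 5.06e-22, and adjusted p = 0.395 with an estimated correlation), as did 37 of 40 G2/M genes (0.35) and 30 of 33 nucleolar and MYC-linked genes (0.34). Those 2 lists had adjusted p = 2.79e-07 and 3.75e-07, and each adjusted p = 0.518 with an estimated correlation. Of 27 lists 11 passed and none with an estimated correlation. In 16 of 135 list tests over the 5 comparisons the median, mean and test differed in sign, and 0 of these passed.

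Cell lines differed from tumours in a large part of the transcriptome: 3292 genes rose and 3137 fell, or 49.0% of those tested, and 5794 of these had no overlap in either genotype. No overlap held for 51.2% of all genes, against 5.6% by chance. The Y-linked genes Eif2s3y, at 108 and 120 CPM in cell lines and at most 0.1 CPM in tumours, Kdm5d, Uty and Ddx3y rose. Xist, expressed from the inactive X, stood at 1469 and 1211 CPM in tumours and 2.7 and 2.6 CPM in cell lines, so the material goes with the sex of the cells. Nov rose to 58.9 and 85.9 CPM from 0.3 or less. Flt3, a receptor of progenitor cells, fell from 22.0 and 18.4 CPM to 0.2 CPM, and the chemokine receptor gene Cx3cr1 fell from 32.6 and 10.9 CPM to 0.3 or less. With a minimum fold of 1.5 the count was 1902.

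All 27 sterol synthesis genes rose in cell lines (median 1.90), such as Fasn, 7.13-fold (log2 2.83, SE 0.10), and Idi1, 6.05-fold (camera adjusted p = 4.76e-31, and adjusted p = 0.163 with an estimated correlation). Of 33 nucleolar and MYC-linked genes 32 rose, such as Hspd1 (1.49, SE 0.07) (median 0.92, adjusted p = 4.56e-21, and adjusted p = 0.163 with an estimated correlation). Of 30 ATF4 and ER stress genes 23 rose and 2 fell (Psat1 1.72, SE 0.08; adjusted p = 1.08e-10, and adjusted p = 0.149 with an estimated correlation). Cytokine (STAT5) response genes rose in 14 of 22 and fell in 1, with Cish 28.9-fold and Pim1 11.2-fold higher (adjusted p = 9.33e-06, and adjusted p = 0.163 with an estimated correlation). Glycolysis and hypoxia genes rose in 16 of 31 and fell in 5 (Slc2a1 2.06; adjusted p = 0.00199, and adjusted p = 0.223 with an estimated correlation). Of 31 p53 target genes 23 rose and 3 fell, with Zmat3 at 3.45 and Plk3 at 2.44 (adjusted p = 1.62e-06, and adjusted p = 0.357 with an estimated correlation). Secretory and inflammatory genes rose in 9 of 19 and fell in 3, with Ccl3 at 1.71 (SE 0.13). Their median was 1.25 (camera adjusted p = 0.0367, and adjusted p = 0.223 with an estimated correlation). The call ended with library size alone (median 1.30, adjusted p = 0.0566) and with a filter of 5 CPM in 2 libraries (0.83, 0.171). Without the line labelled Hhex-/fl 2 the median was 1.18.

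Of 38 interferon response genes 37 fell in cell lines, with a median of -1.63, such as Oas2 (-2.35, SE 0.13) and Irf9 (-1.60, SE 0.07) (camera adjusted p = 7.93e-28, and adjusted p = 0.163 with an estimated correlation). Neutrophil maturation genes fell in 17 of 38, such as Csf3r (-1.70, SE 0.11), the granulocyte colony-stimulating factor receptor gene (adjusted p = 2.04e-05, and adjusted p = 0.642 with an estimated correlation). Monocyte and macrophage genes fell in 16 of 37 and rose in 4, with Csf1r at -2.35 (adjusted p = 0.00274, and adjusted p = 0.612 with an estimated correlation). Mast cell, basophil and eosinophil genes fell in 7 of 11 (adjusted p = 0.00199, and adjusted p = 0.223 with an estimated correlation) and dendritic cell and MHC class II genes in 6 of 13, with Cd74 at -3.37 (adjusted p = 0.00495, and adjusted p = 0.163 with an estimated correlation). The other 15 lists did not pass. Among them, 10 of 25 MLL-fusion target genes rose and 5 fell, with Hoxa9 at 0.85 (SE 0.12), 4 of 12 primary granule genes rose and 7 fell, with Elane at -0.92 (SE 0.17), and 2 of 7 CDK inhibitors rose and 2 fell, with Cdkn1a at 2.10 and Cdkn1c at -3.94.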

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

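All tests of explanations here were chosen after the results were seen, and the tests of the difference between responses were fixed before the data were examined.

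Hhex differed between the responses of tumours and cell lines by -1.90 on the log2 scale, adjusted over the list alone (edgeR adjusted p = 0.000447), lower in Hhex-/fl tumours and higher in cell lines labelled Hhex-/fl in each library. Exchanged genotype labels of the cell lines are argued against, since 25 of the 27 genes called in tumours kept their sign in cell lines. Scaling between libraries was not decided: the lowest Hhex change in cell lines under 3 other scalings was 1.05, but these hardly move any gene and could not have turned it. Reads from parts of Hhex that a deletion leaves cannot be told apart from an intact transcript, since the 99.8 CPM in cell lines labelled Hhex-/fl come from 1 count per whole gene. A biological difference between cultured and bone marrow leukaemia in Hhex expression also stays open, untested. It could not be told from sex or animal of origin, since cell lines expressed Y-linked genes and tumours Xist.

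Interferon response genes differed between the responses by a median of 0.82 (camera adjusted p = 4.96e-23; adjusted p = 0.293 with an estimated correlation), with a median of 1.37 in tumours and 0.64 in cell lines (1.25 and 0.26 with a ribosomal RNA covariate). A large added share of lymphoid, erythroid, megakaryocytic, dendritic, mast or stromal cells in the Hhex-/fl tumours is argued against. The largest rise of their summed marker CPM, 51.5 in mast cell genes, was 2.8% of the interferon rise of 1849 CPM. A small share stays open, since few markers were summed (8 T and NK and 2 B lineage genes). T and NK (1.37) and erythroid (1.12) medians were as high or nearly so, from few counts (rises of 26.5 and 22.1 CPM). The test of summed markers first held monocytes too, at 15.2%, and they were moved to the next. A larger share of maturing neutrophils or monocytes stays open: the smallest interferon difference between libraries, 1.27, exceeded the largest rise between libraries in neutrophil (1.05) and monocyte (0.14) genes, but the high baseline of those markers would hide a small share, and a sort on GFP is not tied to these samples. Ribosomal RNA content as a cause was not decided. The median was 1.25 with the covariate, but its slope comes only from differences between the 2 libraries of a group. Those ran the same way by replicate number in both genotypes of each material. The share was at most 0.59% in libraries labelled Hhex-/fl and at least 0.75% in the others. The fit therefore cannot part ribosomal RNA from replicate or genotype differences. Called members went from 12 to 0, with 1 residual degree of freedom fewer and wider errors, such as Oas2 from 2.45 (SE 0.18) to 2.13 (SE 0.20). An effect of genotype or of the animals stays a hypothesis.

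Chpf and Tmem198 were higher together in libraries labelled Hhex-/fl. A constant share of Chpf reads counted to Tmem198 is argued against, since the mean ratio of Tmem198 to Chpf was 2.02 times as high in Hhex-/fl tumours as in cell lines labelled Hhex-/fl. A change of the wider neighbourhood is too: the 4 nearest genes at 5 CPM or more, Dnpep, Gmppa, Stk11ip and Farsb, moved by at most 0.23. The CPM minimum was added after a first form without it gave 2.59 for Speg (SE 2.02), at a mean of 3.42 CPM. Whether Speg itself changed stays open, given that SE. Gmppa lies between Speg and the pair, and moved by 0.10 (SE 0.11) in tumours and 0.20 (SE 0.11) in cell lines. These values argue against an unbroken change covering Chpf, Tmem198 and Speg. A change confined to the pair stays open. A biological effect of Hhex on the pair may be followed up beside it, as a hypothesis.

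Cdkn2b differed between responses by -1.61, with log2 2.68 in tumours and 4.28 in cell lines. It passed adjusted over the list alone (edgeR adjusted p = 0.0481) and not over all genes (0.42). Its Hhex+/fl values, given above, lie near the floor in both materials. Padi2 moved in opposite directions without overlap, with a difference of -2.34 (edgeR adjusted p = 0.0814). Glipr1 did so too, with -0.93 in tumours and 0.57 in cell lines, a difference of -1.50 (edgeR adjusted p = 0.242).

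Further lists differed between the responses by camera with a preset correlation, none with an estimated one. The adjusted p of 6 of them rose above the threshold in other fits, given with their medians, some of which stayed as large. G1/S genes differed by 0.56 (adjusted p = 5.06e-22), G2/M genes by 0.35 (2.79e-07; 0.21 without the line labelled Hhex-/fl 2) and nucleolar and MYC-linked genes by 0.34 (3.75e-07). ATF4 and ER stress genes differed by 0.28 (0.0314), and by 0.27 (0.0514) without Hhex+/fl tumour 1, 0.20 (0.0697) without Hhex+/fl cell line 2, 0.12 (0.0836) without Hhex-/fl tumour 2, 0.39 (0.0914) or 0.15 (0.0845) without the line labelled Hhex-/fl 1 or 2, and 0.18 (0.22) with a filter of 5 CPM in 2 libraries. P53 target genes differed by -0.38 (0.00344), and by -0.16 (0.0705) without Hhex+/fl cell line 1, -0.34 (0.182) without Hhex-/fl tumour 1 and -0.05 (0.119) without the line labelled Hhex-/fl 2. Monocyte and macrophage genes differed by -0.64 (0.0314), and by -0.21 (0.752) without Hhex+/fl tumour 1, -0.54 (0.0705) without Hhex+/fl cell line 1, -0.76 (0.1) or -0.57 (0.0836) without Hhex-/fl tumour 1 or 2, 0.01 (0.59) without the line labelled Hhex-/fl 2, and -0.31 (0.282) with the ribosomal RNA covariate. Without other libraries these lists differed by more, such as -0.98 for monocyte genes without Hhex+/fl tumour 2 and -0.63 for p53 target genes without Hhex+/fl cell line 2. Secretory and inflammatory genes differed by -0.79 (0.00736), and by -0.43 without the line labelled Hhex-/fl 2. T and NK lineage genes differed by 1.33 (0.0169), and by 1.67 (0.0501) without the line labelled Hhex-/fl 1, 1.66 (0.0992) with no filter and 0.69 (0.0208) without Hhex-/fl tumour 2. Megakaryocyte and platelet genes differed by -0.95 (0.0191), and by -0.60 (0.0896) without Hhex+/fl tumour 2, -0.49 (0.132) without Hhex+/fl cell line 1, -0.20 (0.443) without the line labelled Hhex-/fl 2, -0.68 (0.114) with no filter and -0.79 (0.0874) with the ribosomal RNA covariate. Stromal and endothelial genes differed by -0.78 (0.0104), and by -0.52 (0.0836) without Hhex-/fl tumour 2, -0.18 (0.0565) without the line labelled Hhex-/fl 2, 0.19 (0.435) with no filter and -1.45 with a filter of 5 CPM in 2 libraries.

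Other splits of the 8 libraries do not exclude chance for the averaged genotype comparison: 7 of 34 splits, the real one included, called at least its 39 genes, and the highest other called 558. The 6 splits that part the cell lines by replicate number called 119 to 558 genes and the other 27 at most 0, which points to a structure of the samples, so the count reflects that structure and does not measure chance alone. For cell lines against tumours 1 of 34 splits, the real one, called 6429 genes, and the highest other 0. Each other split mixes tumours with cell lines, which puts their large difference into the residual spread. The splits therefore cannot exclude a chance difference between the animals or cultures behind these libraries.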

How the results depend on the processing

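The limma-trend fit to log2 RPKM and the ribosomal RNA covariate were chosen after the results were seen. Across alternatives no named gene that passed the test in a comparison changed direction there; values near 0, such as those of Ezh2, did. The counts of calls moved, and unless the construction of an alternative shows the cause, the cause was not tested.

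Genes called in tumours, in cell lines, averaged and as a difference between responses numbered 27, 1, 39 and 0. DESeq2 called 349, 344, 462 and 116, and no filter 72, 3, 98 and 1. Limma-voom called 55 in tumours and 22 averaged, with quality weights 331 and 20. Fits of only the 4 libraries compared called 337 and 0 in tumours and cell lines. Log2 RPKM gave 66 and 0, the ribosomal RNA covariate 1, 0 and 0 in the first 3, a minimum fold of 1.5 gave 9 in tumours, 7 averaged and 1902 between materials (6429 without it), and the additive model 11 averaged. Leaving out 1 library gave 0 to 32, 0 to 2, 1 to 100 and 0 calls, 4464 to 6595 between materials, 0 to 2 shared genes and 17 to 23 lists. The 1 shared gene became 47 in DESeq2, 3 with no filter and 0 with only the 4 libraries, log2 RPKM or the covariate. The 21 of 54 list calls became 0 with an estimated correlation and 5 in fry for 1 direction.

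Replicate numbers are shared between groups, with 2 pairs per material and nothing in the labels tying them; differences between replicates 1 and 2 correlated across genes between genotypes at 0.104 in tumours and 0.885 in cell lines. A replicate block gave 40, 1, 48 and 0 genes, 6569 between materials, 21 lists and 1 shared gene. A replicate block within each material gave 873 (432 higher, 441 lower), 1474 (837 higher, 637 lower), 1603 and 305 genes and 156 shared, and put immediate early (0.0645) and megakaryocyte (0.0656) genes in tumours above the threshold; Hhex, Cdkn2a and Cdkn2b passed in both materials.

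Neutrophil maturation genes turned from 0.65 to -0.43 in tumours, from 0.48 to -1.31 in cell lines and from 0.78 to -0.96 averaged with the ribosomal RNA covariate, and in cell lines to -0.04 without Hhex+/fl replicate 1 and -1.34 without the line labelled Hhex-/fl replicate 2, the lowest of a range up to 1.65. Stromal and endothelial genes turned from -0.12 to 0.22 in tumours with no filter and to 0.13, 0.14 and 0.14 without Hhex+/fl tumour 1 or Hhex+/fl cell line 1 or 2. Of list values in tumours, called or not, 442 kept their side of the threshold, 54 lost and 15 gained a call, and 2 called ones turned. In cell lines it was 472, 22, 16 and 3. Direction was compared only for called lists. Lists not called could change sign, such as B lineage genes, with medians from -1.10 to 1.33 in tumours and -0.33 to 0.91 in cell lines. The sample files were not run as counts because they hold log2 RPKM. Changes of 2-fold were recovered in 20% of simulated genes in tumours; how much of this depth sets was not tested.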

Other observations

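The gene families and the test here were chosen only after the results were seen.

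Genes of the cytosolic ribosome were slightly lower in Hhex-/fl tumours: 1 of 82 was positive, the median log2 fold change was -0.39, and 42 fell adjusted over the list alone (camera adjusted p = 1.42e-22, and adjusted p = 0.284 with an estimated correlation). Ribosomal RNA reads were lower there too, at 0.34% and 0.59% of counts against 0.75% and 2.15%. With the ribosomal RNA covariate the median was -0.27 with 8 of 82 positive, and 0 fell adjusted over the list alone (adjusted p = 1.98e-05, and adjusted p = 0.864 with an estimated correlation). Schlafen genes, many of which interferon induces, were positive in 7 of 8 in tumours (median 1.17), where 4 rose and 1 fell adjusted over the list alone (adjusted p = 2.91e-08, and adjusted p = 0.0696 with an estimated correlation); their median was 0.75 with the covariate. In cell lines labelled Hhex-/fl, histone genes had a median of -1.59, with 7 lower adjusted over the list alone (adjusted p = 1.07e-09, and adjusted p = 0.284 with an estimated correlation), and in tumours -0.45 (adjusted p = 0.0239, and adjusted p = 0.578 with an estimated correlation). With the covariate the histone medians were -0.14 in cell lines (adjusted p = 0.0889) and 0.40 in tumours (adjusted p = 0.435). Ribosomal RNA reads were lower in the cell lines labelled Hhex-/fl as well, at 0.51% and 0.24% of counts against 1.68% and 1.27%, and most histone transcripts, like ribosomal RNA, lack a poly(A) tail. Mitochondrial ribosomal protein genes had a median of -0.22 in those lines (-0.25 with the covariate), with 7 of 77 positive (adjusted p = 2.3e-09, and adjusted p = 0.284 with an estimated correlation). These directions were the same under 3 other scalings.

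All 7 chaperonin subunit genes rose in cell lines against tumours (median 0.52), as did 16 of 18 cytosolic tRNA synthetase genes (0.68) and 58 of 77 mitochondrial ribosomal protein genes (0.48). Camera gave these 3 families adjusted p = 9.77e-05, 3.09e-08 and 9.09e-10, and each adjusted p = 0.2 with an estimated correlation. Proteasome subunit genes rose in 32 of 38 and fell in 4 (adjusted p = 1.71e-05, and adjusted p = 0.4 with an estimated correlation). Of 21 integrin genes 2 rose and 12 fell (median -0.64, adjusted p = 0.00219, and adjusted p = 0.2 with an estimated correlation).

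A hypothesis was that linked DNA around the Hhex allele changes its neighbours. Of the 20 nearest tested genes on each side, 11 of 40 had an unadjusted p under 0.05 in the averaged comparison, or 27.5% (one-sided Fisher's exact test, p = 0.045). Windows of 10 and 40 genes on each side, added after this was seen, gave 2 of 20 and 16 of 80 genes (one-sided Fisher's exact test, p = 0.85 and 0.2). With 1 of 3 windows past the threshold, the hypothesis stays undecided.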
